A study of Mus musculus with 6 samples.

How the data were processed

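The series holds RNA-seq of 6 mouse libraries, 2 each from the infrapatellar fat pad, the rectus femoris and the Achilles tendon. Groups were taken from the label that names the 3 tissues, since the source and tissue labels name the fat pad for every library. The submitters' processing notes name Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 with the mouse build GRCm39, without saying which step each served. The counting method, the strand setting, the annotation release and any gene filter are not given in the sources used here.

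For each tissue the authors deposited 1 table of whole-number read counts per Ensembl gene, not normalized, listing 20516 genes in the fat pad and 17120 in muscle and in tendon. The authors also deposited a table per tissue with TPM (abundance scaled by transcript length and library size) for protein-coding genes, with 18402, 15334 and 16520 genes. The same deposited tables give the authors' log2 fold change of library 1 over library 2, the mean log2 CPM, a p-value, its −log10 and an adjusted p-value, per the file headers. The authors' test and its adjustment are not given in the sources used here, and a p-value from 1 library on each side rests on an assumed spread. Of the authors' comparisons, only the log2 fold change, for correlations, and the count of genes past an adjusted p of 0.05 were used. The number of per-sample columns left unused was 0. In the fat pad the TPM columns followed the counts, and in muscle and tendon they did not, so counts served as the main values throughout and TPM only where named.

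Gene symbols came from the authors' tables for 18924 genes and from a names table for 1740, and 8 genes had no symbol. Of 20672 genes in any count table, the 16964 listed in all 3 entered the comparisons between tissues. Coordinates are not given, because the files are on GRCm39 and the annotation at hand, GENCODE M21 on GRCm38, was used only for names and for the share of a gene's exonic bases that another gene also covers, which marks counts that reads could be split over. Without a stated strand setting, sense and antisense genes cannot be told apart.

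Tissues were compared with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M-values scaling, filterByExpr, a fit of all 6 libraries with 1 term per tissue, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05). After filtering 15856 genes were tested, with a biological coefficient of variation of 0.336. Standard errors are the log2 fold change divided by the square root of the F statistic. Where both libraries of a tissue had 0 counts, the fold is a lower bound against 3 counts per library.

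Within a tissue, library 2 was divided by library 1 after TMM scaling with a prior count of 2, over genes with at least 100 counts in the higher library. The 95% intervals are exact conditional binomial intervals of the counts. Where 1 library had 0 counts, the fold is a lower bound against 3 counts in that library. Each pair was also tested with edgeR against the spread between the libraries of the other 2 tissues (16364 genes), and a difference by library number was tested with tissue in the model (15856 genes). Labels give no treatment within a tissue, so neither test is a test of letrozole. The libraries of each pair differed in their counts by more than sampling noise.

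Before the data were examined, the tests, the rule for named genes, the alternatives to be tried and 29 gene lists with 395 genes were fixed. The lists are adipocyte, brown and beige thermogenic, lipogenesis (fatty acid and triglyceride synthesis), fast muscle, slow muscle, muscle atrophy, tenocyte, cartilage, bone and osteoclast, synovial lining, collagen and matrix assembly, matrix proteases and inhibitors, macrophage, lymphocyte, neutrophil and marrow, erythroid, endothelial, smooth muscle and pericyte, Schwann cell, epidermis, sex steroid synthesis and receptors, pain mediators and neurotrophins, inflammatory cytokines, interferon response, immediate early and stress, circadian clock, glucocorticoid response, oxidative phosphorylation, and cell cycle. Between tissues, the named genes are the 10 highest and 10 lowest by log2 fold change among called genes with a mean of at least 50 CPM in the higher tissue and no overlap between the libraries. Between libraries they are the 12 highest and 12 lowest by log2 ratio with at least 100 counts in the higher library. Predicted or unnamed genes and immunoglobulin or T cell receptor segments were counted but not named, and list members could be named with their values. Some list members are not reported here.

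Lists were tested between tissues with camera (limma 3.58.1, on voom values) with a preset correlation of 0.01 and with an estimated one, and with fry. Within a tissue a list's median log2 ratio, over members with at least 20 counts in the higher library, was placed among 10000 random lists of the same size matched on mean expression in 20 bins, for lists with at least 3 members. The genes of a random list were drawn independently, so a list whose genes vary together leaves their range more easily. A place outside that range is a description of the libraries and no test. Alternatives were DESeq2 1.42.0, other scalings, other filters, a replicate block, leaving out each library, other count minimums and a prior count of 0.5. Added after seeing the data were TPM between tissues, tested with limma on log2(TPM + 0.1) for genes with a mean of at least 1 TPM in 1 tissue, and a minimum of 10 counts in the lower library of a pair.

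The procedures were tested on simulated counts with 100 genes changed by 2-fold and 100 by 4-fold. Every library was drawn from the same mean profile with the same dispersion of 0.113 for every gene, without repeated runs. The tissues differ in many more genes, so these rates need not carry over to the real contrasts. For the fat pad against muscle edgeR recovered 3% of the former and 49% of the latter over 15694 genes, with 5 false calls among 57. For a pair against the spread of the others, it recovered 0% and 4% over 15948 genes, with 0 false calls among 4. For the library number it recovered 14% and 93% over 15743 genes, with 9 false calls among 116. DESeq2 made more false calls on the same simulated counts, 23 among 110 for the tissues, 7 among 33 for a pair and 19 among 138 for the library number. It recovered 12% and 75% for the tissues, 3% and 23% for a pair, and 26% and 93% for the library number. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.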

Results

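RNA was sequenced from 3 tissues of the mouse hind limb, with 2 libraries each from the infrapatellar fat pad (the fat body behind the kneecap ligament), the rectus femoris (a fast thigh muscle) and the Achilles tendon. The series concerns letrozole, a drug that blocks aromatase, the enzyme encoded by Cyp19a1 that turns androgens into oestrogens, and the joint pain met under such drugs. The drug's name stands in the titles of both fat pad libraries and in none of the other 4 titles, and no label marks a treated and a control library within a tissue. Letrozole and control were therefore not compared. If that name marks treatment, an effect of the drug and an effect of the tissue cannot be told apart where the fat pad is compared. The tissues were compared with each other, and library 2 was set against library 1 within each tissue, as in the authors' deposited comparisons. The labels do not say that the libraries of a tissue came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

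Depth was 83132413 and 106319037 counts in the fat pad libraries, 56216295 and 58544836 in muscle, and 59042675 and 62063826 in tendon. A count of 0 allowed a level of up to 0.0361 and 0.0282 CPM (counts scaled to library size) in the fat pad libraries, 0.0534 and 0.0512 in muscle, and 0.0508 and 0.0483 in tendon, taking 3 counts as the limit. Intervals and limits given here cover counting error only. The libraries of a pair differed by far more than sampling noise, with a chi-square per degree of freedom of 303 in the fat pad, 75.6 in muscle and 506 in tendon, and were kept as separate samples. All 6 libraries carry the same batch label, while the titles of each tissue share a code of their own. The titles do not say what that code marks, so its effect and an effect of the tissue cannot be told apart. The fat pad and tendon titles also end in the word combined, without saying what was combined, and the muscle titles do not.

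The source and tissue labels name the fat pad for all 6 libraries, while another label names the 3 tissues, and the marker genes differed by the latter. Cfd, which encodes the adipocyte protease adipsin, stood at 56291 and 61961 CPM in the fat pad libraries, at 113 and 384 in muscle, and at 1714 and 218 in tendon. Myh4, the fastest myosin heavy chain, stood at 69991 and 74736 CPM in muscle and at 14.4 and 8.62 in the fat pad. Tendon library 2 held 22606 CPM of Myh4 and tendon library 1 held 783. Col1a1, a chain of the main tendon collagen, reached 12678 and 7291 CPM in tendon, 724 and 559 in muscle, and 511 and 297 in the fat pad. S100a8, a calcium-binding protein of neutrophils, stood at 666 CPM in fat pad library 1 and 95.3 in library 2, and at 1.69 or less in the other 4 libraries.

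**Figure D1:**
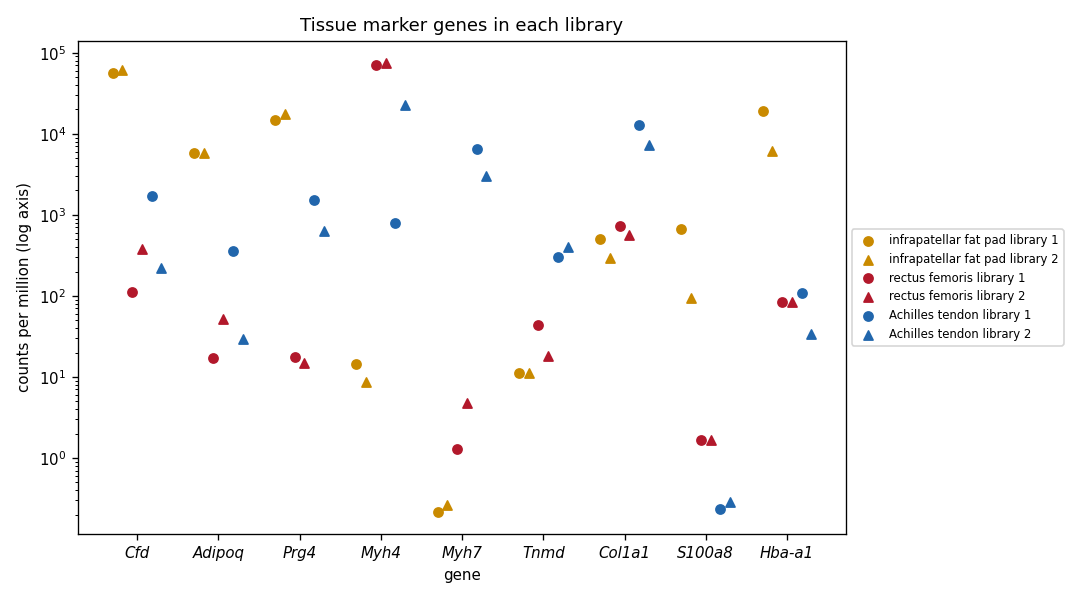
Levels of 9 tissue marker genes in CPM of the library total (log axis), with 1 point per library, circles for library 1 and triangles for library 2. Cfd lies at 56291 and 61961 in the fat pad and at 1714 or less elsewhere, while Myh4 lies at 783 and 22606 in the tendon libraries.

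Cyp19a1 (ENSMUSG00000032274), the enzyme that letrozole blocks, had 0 counts in both fat pad libraries, which allows up to 0.0361 and 0.0282 CPM. The muscle and tendon counts do not list this gene, so no level can be given there. Esr1, the oestrogen receptor alpha, was counted in every library, with 2316 and 1976 counts in the fat pad, 1846 and 2235 in muscle, and 2731 and 1306 in tendon. Gper1, a membrane receptor that responds to oestrogens, had 732 and 753 counts in the fat pad, 104 and 108 in muscle, and 373 and 145 in tendon. Esr2, the oestrogen receptor beta, had 10 counts or fewer in each library, and Pgr, the progesterone receptor, had 52 counts or fewer.

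Adipocyte, synovial lining and blood cell genes stood higher in the fat pad than in the muscle, and muscle and tendon genes stood lower. Adipoq, the adipocyte hormone adiponectin, averaged 5414 ± 141 CPM in the fat pad and 45.4 ± 30.9 in muscle (SD, n = 2 each, scaled by trimmed mean of M-values, TMM), a log2 fold change of 6.90 ± 1.26 (SE; adjusted p = 0.00308 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Prg4, the joint lubricant lubricin, averaged 15121 ± 2335 CPM in the fat pad and 21.9 ± 3.72 in muscle, a log2 fold change of 9.43 ± 0.68 (adjusted p = 6.89e-05 by the same test). Myh4 averaged 10.7 ± 3.60 CPM in the fat pad and 96378 ± 46.6 in muscle, a log2 fold change of -13.14 ± 2.06 (adjusted p = 0.00153 by edgeR's test). edgeR's test called 4728 of 15856 genes higher in the fat pad and 4698 lower at a Benjamini-Hochberg rate of 0.05, of which 4012 and 3939 differed by at least 2-fold.

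Among the other genes highest in the fat pad over muscle, Vsig4, a complement receptor of resident macrophages, had a log2 fold change of 11.92 ± 0.58, and Has1, which makes hyaluronan, 9.89 ± 0.85. Rspo2, a secreted enhancer of Wnt signalling, had 9.64 ± 0.67, and the neutrophil granule genes Ltf and Ngp had 10.61 ± 1.58 and 10.25 ± 1.32. Bglap2 (osteocalcin) averaged 104 ± 5.97 CPM in the fat pad and had 0 counts in muscle, at least 1493-fold higher against a limit of 3 counts per library. Bglap2 and Bglap are near-identical copies, so their counts are uncertain. The genes with 0 counts in the fat pad included Trim72, which takes part in sealing torn muscle membranes, and Fitm1, a lipid droplet protein of muscle, at least 10165-fold and 8850-fold lower than in muscle. Myh1, another fast myosin, had a log2 fold change of -14.41 ± 1.06, Hrc, a calcium-binding protein of the sarcoplasmic reticulum, -13.31 ± 0.51, and Actn3, the actinin of fast fibres, -12.14 ± 1.66. Adjusted p-values of these genes lay between 3.64e-05 and 0.00123 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

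By list, 16 of the 18 adipocyte genes were higher in the fat pad and 1 was lower (16 and 2 when adjusted over the list alone), with a median log2 fold change of 3.55. All 15 fast muscle genes were lower (median -10.22), as were 9 of the 10 slow muscle genes (-3.60) and 10 of the 13 tenocyte genes (-2.77, with 1 higher). Of the 8 synovial lining genes 6 were higher and 1 lower (6.05), of the 15 macrophage genes 11 were higher (3.21), and of the 15 lymphocyte genes 12 (5.18, or 4.97 with genes at 0 held at their limit). Of the 9 erythroid genes 8 were higher (6.68, or 5.77 at the limit), Hba-a1, a haemoglobin chain, with a log2 fold change of 6.71 ± 0.86. Counts adjusted over the list alone were the same for the other lists just named. These 8 lists, 5 up and 3 down, were called by camera with a preset correlation of 0.01 between genes, with adjusted p from 2.99e-08 for fast muscle to 0.0325 for slow muscle. None of the 8 calls held when camera estimated the correlation (adjusted p = 0.745 to 0.862). For the synovial lining list that estimate was -0.0078, below the preset value, and camera's unadjusted p still rose from 0.00237 to 0.0515. The lost calls therefore cannot be put down to correlation between genes alone. All 12 neutrophil and marrow genes were higher (median 7.31, or 6.93 at the limit), with a camera adjusted p of 0.0574. In the TPM columns 3 of 5 of these genes and 6 of 13 lymphocyte genes were called higher (medians 4.59 and 3.40). Within the fat pad, library 2 over library 1 had median log2 ratios of -2.67 on the neutrophil list, with S100a8 at 666 and 95.3 CPM, and of -1.76 on the erythroid list, with Hba-a1 at 19127 and 6059.9 CPM. Within muscle the slow muscle list had 1.01 and the lymphocyte list 1.23.

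Oestrogen receptor Esr1 averaged 21.6 ± 5.69 CPM in the fat pad and 47.2 ± 2.82 in muscle, a log2 fold change of -1.13 ± 0.34 (adjusted p = 0.0263 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call was lost with scaling by total counts (-0.61, adjusted p = 0.202), without fat pad library 2 (-0.89, 0.136), without muscle library 1 (-1.19, 0.0707) and without muscle library 2 (-1.07, 0.0991). Ptges, which makes prostaglandin E, averaged 78.1 ± 55.8 CPM in the fat pad and 11.4 ± 3.91 in muscle, a log2 fold change of 2.78 ± 0.54 (adjusted p = 0.00397 by edgeR's test). In the TPM columns Esr1 had -1.71 and Ptges 1.75, both called by limma. If the drug's name in the fat pad titles marks treatment, its effect on these genes cannot be told apart from the tissue.

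Fold changes between tissues are relative to TMM scaling. Scaling by total counts alone moved the median gene by 0.52 for fat pad over muscle, -0.21 for fat pad over tendon and 0.73 for tendon over muscle on the log2 scale, and scaling by DESeq2's size factors moved it by 0.04, 0.11 and -0.07. With total counts, 6350 genes were higher in the fat pad than in muscle and 3420 lower. In the TPM columns, tested with limma, 3069 genes were higher and 5863 lower for fat pad over muscle, 1530 and 7901 for fat pad over tendon, and 4075 and 451 for tendon over muscle.

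Adipocyte, synovial lining and blood cell genes stood higher in the fat pad than in the tendon, and matrix, tendon and muscle genes stood lower. Col1a1 averaged 375 ± 134 CPM in the fat pad and 7931 ± 2421 in tendon (SD, n = 2 each), a log2 fold change of -4.40 ± 0.49 (adjusted p = 0.000345 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Scx, a transcription factor of tendon cells, had a log2 fold change of -5.03 ± 0.56 and Tnmd, the tendon membrane protein tenomodulin, -4.80 ± 0.50 (adjusted p = 0.000366 and 0.000283 by edgeR's test). Adipoq was higher in the fat pad by a log2 fold change of 5.20 ± 1.16, and S100a8 by 10.67 ± 1.14 (adjusted p = 0.00764 and 0.000303 by edgeR's test). edgeR's test called 4308 of 15856 genes higher in the fat pad and 4972 lower, 3557 and 4242 of them by at least 2-fold.

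The tendon libraries also carried muscle transcripts. Myh7, the slow myosin heavy chain, averaged 0.224 CPM in the fat pad and 3765 ± 1722 in tendon, a log2 fold change of -14.02 ± 0.99 (adjusted p = 8.72e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Myl2, a slow myosin light chain, had a log2 fold change of -12.21, Tnnc1, the slow troponin C, -11.65, and Perm1, a regulator of muscle mitochondria, -11.76. Trim72, Fitm1 and Ostn, a secreted peptide of muscle and bone, had 0 counts in the fat pad and were at least 5686-fold, 2728-fold and 2215-fold lower there. Genes with the highest fold change in the fat pad included the major urinary protein genes Mup18, Mup11 and Mup2 and the osteocalcin genes Bglap2 (11.55) and Bglap (10.36), whose near-identical copies make their counts uncertain. Also among them were S100a8 and other genes of neutrophils and myeloid cells, Ngp (13.49 ± 1.56), Chil3 (10.73), Ltf (10.27) and S100a9 (9.61). In the TPM columns S100a8 had 5.47, Chil3 4.52 and S100a9 3.58, of which the last was not called. Bglap stood at 318 and 227 TPM in the fat pad and at 0.633 and 1085 in tendon, so that tendon library 2 lay above both fat pad libraries there.

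By list, all 15 fast and all 10 slow muscle genes were lower in the fat pad than in tendon (medians -7.67 and -9.23), as were 12 of the 13 tenocyte genes (-5.97) and 15 of the 20 collagen and matrix assembly genes, with 1 higher (-1.97; 16 lower when adjusted over the list alone). Of the 10 smooth muscle and pericyte genes 6 were lower (-1.92). Higher in the fat pad were 10 of the 18 adipocyte genes, with 1 lower (2.27), 10 of the 18 lipogenesis genes, with 3 lower (2.17), and 6 of the 8 synovial lining genes, with 1 lower (4.54). So were 12 of the 15 macrophage genes, with 1 lower (3.24), 11 of the 15 lymphocyte genes (5.03; 12 when adjusted over the list alone), 8 of the 9 erythroid genes (6.85), and all 12 neutrophil and marrow genes (9.51, or 9.42 at the limit). Of the 12 bone and osteoclast genes 6 were higher (2.36), of the 14 interferon genes 5 (2.00), and of the 13 cell cycle genes 7 (1.51; 6 when adjusted over the list alone). The signs of the bone and cell cycle medians turned in the TPM columns, to -2.49 and -0.26. Fewer genes were called there for lymphocytes (1 of 13 higher, median 0.95), neutrophils and marrow (1 of 5, 3.58) and interferon (2 of 14 with 1 lower, 0.08), and the adipocyte median was 0.88. Counts adjusted over the list alone were the same for the other lists just named. The tendon libraries stood apart on several of these lists in the median log2 ratio of library 2 over library 1. The median was -2.41 for adipocytes, with 15 of 18 genes at least 2-fold lower. It was -1.48 for lipogenesis, -1.51 for erythroid, -1.09 for smooth muscle and 1.38 for fast muscle genes. The neutrophil median of -1.19 rested on 4 genes and lay within the range of its random lists, -2.24 to 1.01. Within the fat pad the ratios were -2.67 for neutrophil, -1.76 for erythroid and -1.02 for cell cycle genes. camera called these 15 lists with the preset correlation, with adjusted p from 2.57e-06 for fast muscle to 0.0451. None of the calls held with an estimated correlation, where adjusted p = 0.560 to 0.713 with an estimated correlation. Over the same contrast Esr1 (log2 fold change -0.30) had an adjusted p of 0.475 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and without tendon library 1 it turned to 0.31, while in the TPM columns limma called it at -0.92.

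The tendon libraries stood above the muscle in tendon, cartilage and slow muscle genes and below it in fast muscle and mitochondrial genes. Chad, a matrix protein of cartilage and tendon, averaged 1708 ± 123 CPM in tendon and 32.6 ± 3.31 in muscle (SD, n = 2 each), a log2 fold change of 5.71 ± 0.32 (adjusted p = 0.00282 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Myh7 averaged 3765 ± 1722 CPM in tendon and 3.96 ± 3.06 in muscle, a log2 fold change of 9.89 ± 0.85, and the slow troponins Tnnc1 and Tnnt1 had 7.87 ± 0.48 and 7.06 ± 0.40 (adjusted p = 0.00391, 0.00282 and 0.00282 by edgeR's test). Actc1, the cardiac form of actin, had a log2 fold change of -5.52 ± 1.21, and Ampd1, the AMP deaminase of muscle, -3.37 ± 0.50 (adjusted p = 0.0214 and 0.00921 by edgeR's test). Both of those calls were lost without either muscle library, at adjusted p between 0.0585 and 0.097, with log2 fold changes of -5.42 and -5.59 for Actc1 and -3.38 and -3.33 for Ampd1. Myh4 averaged 9939.5 ± 13214 CPM in tendon and 96378 ± 46.6 in muscle, a log2 fold change of -3.28 ± 1.37 that was not called (adjusted p = 0.119 by edgeR's test) and was called without tendon library 1 (-2.34), without tendon library 2 (-7.33) and in the TPM columns (-3.99). edgeR's test called 2110 of 15856 genes higher in tendon and 2017 lower, 1691 and 1184 of them by at least 2-fold, and with scaling by total counts 5969 and 398. The count of 4127 genes fell to 43 without muscle library 1, to 19 without muscle library 2 and to 1816 without tendon library 1. The calls of Chad, Myh7, Tnnc1 and Tnnt1 were kept in each of those fits.

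By list, 9 of the 10 slow muscle genes were higher in tendon (median 6.43; all 10 when adjusted over the list alone), as were 11 of the 13 tenocyte genes (2.79; 12 over the list alone) and 14 of the 20 collagen and matrix assembly genes (1.48). Of the 11 cartilage genes 6 were higher (3.64; 8 when adjusted over the list alone), of the 11 matrix proteases and inhibitors 5 (1.42), and of the 10 endothelial genes 4 (0.84; 7 over the list alone). Comp, a matrix protein of cartilage and tendon, had a log2 fold change of 4.95 ± 0.36, and Timp3, which inhibits matrix proteases, 1.72 ± 0.28. Lower in tendon were 9 of the 15 fast muscle genes (-2.66; 12 when adjusted over the list alone), 16 of the 18 oxidative phosphorylation genes (-1.07; all 18 over the list alone) and 3 of the 14 interferon genes (-2.09; 7 over the list alone). Most calls of this contrast were lost when either muscle library was left out, so these list counts rest on both of them. The muscle libraries themselves differed on the interferon list, with a median log2 ratio of library 2 over library 1 of -2.13 and 12 of 14 genes at least 2-fold lower in library 2, and on the slow muscle list (1.01), as did the tendon libraries on the fast muscle list (1.38). The signs of the oxidative phosphorylation and interferon medians turned in the TPM columns, to 0.31 and 0.82. camera called these 9 lists, 6 up and 3 down, with adjusted p from 1.72e-09 for oxidative phosphorylation to 0.0133 for interferon. None of the calls held with an estimated correlation, where adjusted p = 0.359 to 0.890 with an estimated correlation. The fry test, whose p-value asks whether the genes of a set move on balance one way and does not compare the set with other genes, called 15, 15 and 7 of the 29 lists for fat pad over muscle, fat pad over tendon and tendon over muscle.

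Another 10 lists were called by camera in none of the 3 tissue contrasts. For the fat pad over muscle their genes were higher and lower as follows: 3 and 3 of 10 brown and beige thermogenic genes, 6 and 7 of 14 muscle atrophy genes, 2 and 3 of 10 Schwann cell genes, 2 and 0 of 3 epidermis genes, and 4 and 1 of 11 sex steroid genes. They were 4 and 1 of 13 pain mediator genes (4 and 0 when adjusted over the list alone), 8 and 2 of 14 inflammatory cytokine genes (9 and 2), 3 and 6 of 14 immediate early genes, 1 and 7 of 15 circadian clock genes, and 4 and 2 of 10 glucocorticoid response genes (4 and 3). Their camera adjusted p lay between 0.109 for the circadian clock and 0.909 for the thermogenic list. Median and mean log2 fold change differed in sign in 5 lists in this contrast (thermogenic, sex steroid, interferon, immediate early and glucocorticoid), in 2 for fat pad over tendon (sex steroid, pain) and in 4 for tendon over muscle (thermogenic, lipogenesis, circadian clock, glucocorticoid). For matrix proteases in fat pad over tendon, camera's direction was down while the median was 0.11.

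Within the fat pad, library 2 held fewer transcripts of granulocytes, red cell precursors and dividing cells than library 1, more of lipogenic enzymes, and clock genes that split in both directions. There is 1 library on each side, so these values have no replicate check and compare the libraries only. S100a8 had 55356 and 10129 counts, a log2 ratio of library 2 over library 1 of -2.75 (95% interval -2.78 to -2.72), and the neutrophil collagenase Mmp8 had 3253 and 138 counts (-4.84). All 13 neutrophil and marrow genes were at least 2-fold lower in library 2 (median -2.67, below all 10000 random lists matched on mean expression, whose central 95% ran from -0.29 to 0.32). All 9 erythroid genes were lower too (median -1.76), with Hba-a1 at -1.61 and Alas2, which starts haem synthesis in red cell precursors, at -1.97. Of the 13 cell cycle genes 8 were at least 2-fold lower (median -1.02), among them Plk1, a mitotic kinase, with 667 and 92 counts (-3.13).

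The B cell genes Ms4a1 and Cd79a had log2 ratios of -2.63 and -2.30 between the fat pad libraries, while Jchain, the joining chain of secreted antibodies, had 1177 and 6724 counts (2.21). The lymphocyte list had 3 of 15 genes at least 2-fold higher and 5 lower, with a median of -0.84. The interferon list had a median of -0.75, with 4 of 14 genes at least 2-fold lower, among them the antiviral gene Rsad2 (4541 and 1381 counts, -2.02). The macrophage list had a median of 0.52, with 13 of 15 genes above 0 and C1qa, a complement component, at 28106 and 61191 counts (0.82). The adipocyte list had a median of -0.12.

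Lipogenic enzymes stood higher in fat pad library 2. The list had a median log2 ratio of 0.55, above all 10000 random lists, and 7 of its 18 genes were at least 2-fold higher. Fasn, the fatty acid synthase, had 59234 and 152642 counts (1.06), Elovl6, a fatty acid elongase, 13186 and 51198 (1.65), and Pnpla3, a lipid droplet protein induced with lipogenesis, 9837 and 75721 (2.64, 95% interval 2.61 to 2.67). Srebf1, a transcription factor of the same pathway, went the other way at -0.71.

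The clock genes of the fat pad split in opposite directions. Dbp, an output gene of the clock, had 9777 counts in library 1 and 815 in library 2, a log2 ratio of -3.88 (95% interval -3.99 to -3.79), and Ciart, Nr1d2, Per3 and Per2, which act as or with clock repressors, had -2.22, -1.94, -1.72 and -1.58. Arntl, the activator BMAL1 that works in antiphase to Dbp, had 292 and 2667 counts, a log2 ratio of 2.88 (95% interval 2.71 to 3.07), and its partner Npas2 had 2.40. Of the 15 genes of the list 7 were at least 2-fold lower and 2 higher, with a median of -0.99 below all 10000 random lists. The median of the same list was 0.02 in muscle and -0.06 in tendon, and -0.71 and -0.24 in their TPM columns. Since the list holds genes that move in opposite directions, a median alone cannot show whether they split. In counts, 14 of the 15 genes lay within 2-fold between the muscle libraries, and 14 of 15 between the tendon libraries.

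**Figure D2:**
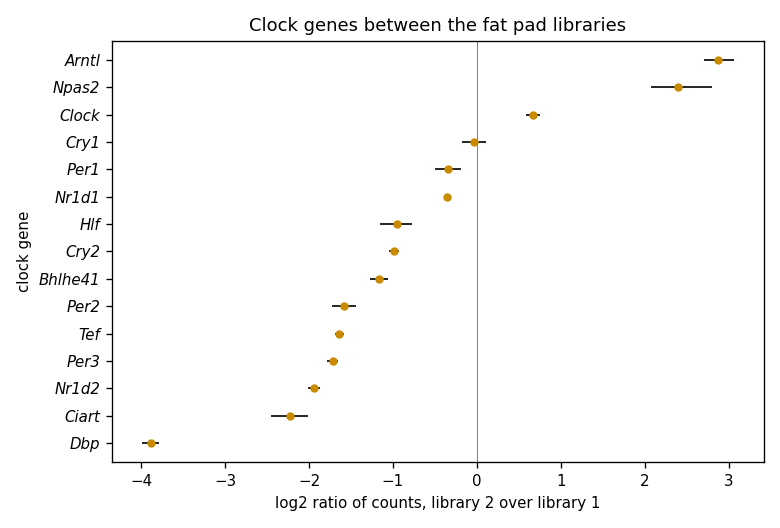
Log2 ratio of counts in fat pad library 2 over library 1 for 15 clock genes, with 95% counting intervals as bars. The values run from -3.88 for Dbp to 2.88 for Arntl, with no replicate check.

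In all, 1501 of 13737 fat pad genes with at least 100 counts in the higher library differed by at least 2-fold, 586 higher and 915 lower in library 2. Of the genes at the ends of that range, Fpr1, a formyl peptide receptor of neutrophils, had 425 counts in library 1 and 0 in library 2, at least 175-fold lower. Prg3, a granule protein of eosinophils, had 331 and 0 counts, at least 136-fold lower, and Ceacam10 had 224 and 0, at least 92.2-fold lower. At the upper end Fxyd3, a regulator of the sodium pump, had 0 and 253 counts, at least 68.3-fold higher, and Tram1l1 had 0 and 412, at least 111-fold higher. Fxyd3 shares 42.5% of its exonic bases with another annotated gene, so its counts are less certain. Septin2 (8394 and 0 counts), Raver1 (1 and 707), Prn (450 and 0), Commd1b and Adnp (997 and 11) share 100%, 99.7%, 96.9%, 99.9% and 82.1% of their exonic bases with another annotated gene, so their counts are uncertain, as are those of the olfactory and vomeronasal receptors and other near-identical family members at both ends. The Septin2 entry given here is ENSMUSG00000116048, whose exonic bases are shared with Sept2. Another entry of the same symbol, ENSMUSG00000026276, was higher in library 2, with a log2 fold change of 1.57 in the fit against the other pairs. Septin2 as a whole was therefore not absent from library 2. Of the 49 genes with fewer than 3 counts in 1 of the fat pad libraries, 48 were in the annotation. Of these 48, 25.0% shared at least 50% of their exonic bases with another gene, against 2.09% of the other annotated genes.

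For the muscle and the tendon, the count columns and the TPM columns of the same library names did not follow each other. Across genes with at least 100 counts in both libraries, the log2 ratio of library 2 over library 1 from counts correlated with that from TPM at r = 1.00 in the fat pad, -0.231 in muscle (rho -0.388, 11381 genes) and -0.239 in tendon (rho -0.314, 12407 genes). Genes are not independent replicates, and these correlations describe the libraries only. Each muscle or tendon value given here therefore comes from the counts unless the TPM columns are named. The ratios of the authors' deposited table correlated with the count ratios at 0.991 in the fat pad, -0.0117 in muscle and -0.0914 in tendon, and with the TPM ratios at 0.880, 0.899 and 0.935. The authors' deposited table listed 758 of 18402 fat pad genes with an adjusted p under 0.05, 9 of 15334 in muscle and 495 of 16520 in tendon, and 1 of the libraries was at 0 in TPM for 690, 9 and 393 of them.

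**Figure D3:**
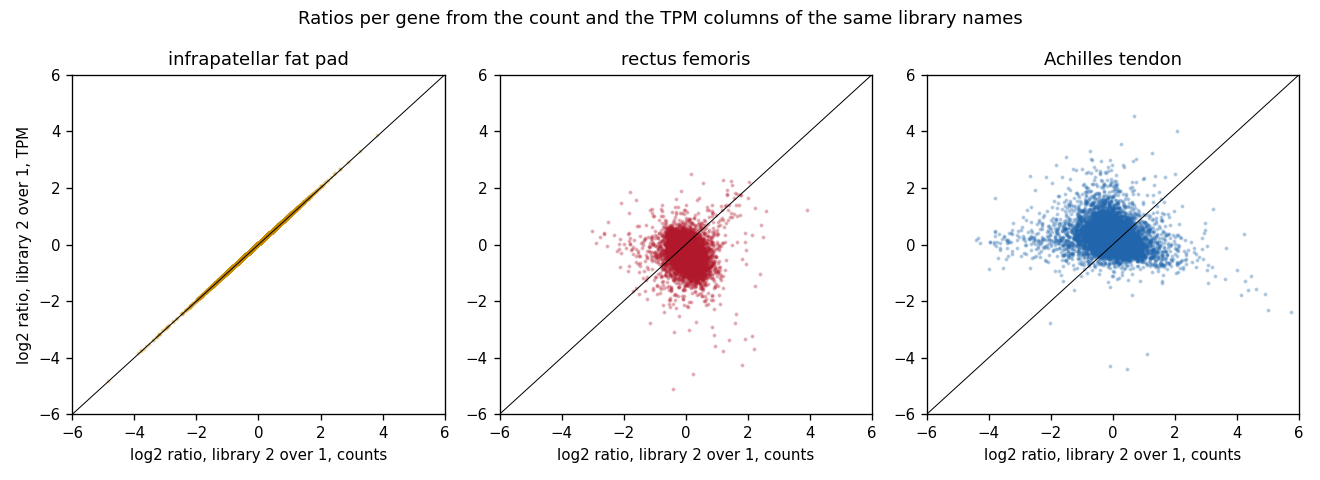
Log2 ratio of library 2 over library 1 for each gene, from counts on the x axis and from TPM on the y axis, with the diagonal marking equal ratios. Points lie on the diagonal in the fat pad (r = 1.00) and off it in muscle (r = -0.231) and tendon (r = -0.239).

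Within the muscle counts, library 2 held fewer transcripts of interferon-induced genes and more of fatty acid synthesis. Ifit3, which is induced by interferon, had 4097 and 563 counts, a log2 ratio of -3.03 (95% interval -3.16 to -2.91), and Irf7, a transcription factor of the interferon response, had 2201 and 394 (-2.65, 95% interval -2.81 to -2.50). Of the 14 interferon genes 12 were at least 2-fold lower, with a median of -2.13 below all 10000 random lists, whose central 95% ran from -0.15 to 0.20. Fasn had 7623 and 45972 counts (2.42, 95% interval 2.39 to 2.46) and Elovl6 366 and 2306 (2.48), and all 18 lipogenesis genes stood above 0 (median 1.02, 10 of them at least 2-fold). The TPM columns of the same library names gave an interferon median of 0.01 and a lipogenesis median of 0.32. With 1 library on each side, these values have no replicate check.

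The slow muscle list had a median log2 ratio of 1.01 between the muscle libraries in counts, with 5 of 10 genes at least 2-fold higher in library 2 (Myh7 with 73 and 278 counts), and -2.50 in TPM. The adipocyte list had 0.93, with 7 of 18 genes at least 2-fold higher and Adipoq at 960 and 3053 counts, and 1.09 in TPM. The tenocyte list had -0.51 in counts, with 0 of 13 genes above 0, and -1.60 in TPM. In all, 327 of 11827 muscle genes with at least 100 counts differed by at least 2-fold, 172 higher and 155 lower in library 2, against 94 higher and 465 lower in the TPM columns. Those at the upper end included Oxtr, the oxytocin receptor (24 and 767 counts, 4.72, 95% interval 4.24 to 5.48), Fndc9 (9 and 235 counts, 4.28), Cyfip2, an actin regulator (3.92), Cish, a suppressor of cytokine signalling (91 and 1205 counts, 3.53), and Ngfr, a neurotrophin receptor (76 and 628 counts, 2.85), while Mmd2 had 0 and 120 counts, at least 35.6-fold higher. Those at the lower end included the interferon list members Oas3 (216 and 24 counts, -3.23) and Ifi44 (-2.89), and Apol9b (-3.63), Apol9a (-2.89) and Ifit3b (-2.76). Raver1 (881 and 0 counts) and H2ac18 (0 and 678) share 99.7% and 100% of their exonic bases with another gene and are uncertain, as are the near-identical pairs Apol9a and Apol9b and Ifit3 and Ifit3b.

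Within the tendon counts, library 2 held far fewer transcripts of Schwann cells and adipocytes and far more of fast muscle. Mbp, a protein of the myelin sheath, had 28244 and 1683 counts, a log2 ratio of -3.97 (95% interval -4.05 to -3.90), and Adipoq had 20883 and 1809 (-3.43, 95% interval -3.51 to -3.37). Pvalb, the calcium buffer of fast fibres, had 9860 and 224523 counts (4.60, 95% interval 4.57 to 4.63), and Myh4 had a log2 ratio of 5.02 (95% interval 5.00 to 5.03). Of the 10 Schwann cell genes 9 were at least 2-fold lower (median -3.48), of the 18 adipocyte genes 15 (-2.41) and of the 18 lipogenesis genes 12 (-1.48), while 13 of the 15 fast muscle genes were at least 2-fold higher (1.38). The Schwann cell median lay below and the fast muscle median above all 10000 random lists, whose central 95% ran from -0.44 to 0.32 for the former. The TPM columns gave medians of 0.14 for Schwann cells, 0.04 for adipocytes, 0.14 for lipogenesis and -0.72 for fast muscle.

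The slow muscle list had a median of -0.86 between the tendon libraries in counts, with 0 of 10 genes above 0 and Myh7 at 386789 and 185330 counts (-0.97). The tenocyte list had 0.56, with Scx at 2556 and 4998 counts (1.06) and Tnmd at 0.60, and the collagen and matrix assembly list had -0.32, which turned to 0.56 in TPM. In all, 1482 of 13153 tendon genes with at least 100 counts differed by at least 2-fold, 525 higher and 957 lower in library 2, against 769 higher and 58 lower in the TPM columns. Those at the lower end included the myelin genes Cldn19 (1975 and 48 counts, -5.21, 95% interval -5.71 to -4.86), Pllp (-5.00), Ugt8a (-4.42) and Mal (3808 and 167 counts, -4.40), and Col6a5, a collagen VI chain, had 483 and 0 counts, at least 151-fold lower. Those at the upper end included the muscle genes Igfn1 (4 and 2432 counts, 8.74, 95% interval 7.98 to 11.22), Mss51 (104 and 5279 counts, 5.73) and Mybph (403 and 11388 counts, 4.91). Commd1b (1732 and 0 counts), Pcdhga10, Zfp708 (0 and 322) and Pllp share 99.9%, 100%, 96.4% and 54.2% of their exonic bases with another gene and are uncertain. Mybph shares 49.9% and is less certain too. Scaling each pair by total counts in place of TMM moved the median by -0.05 in the fat pad, 0.11 in muscle and -0.16 in tendon.

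**Figure D4:**
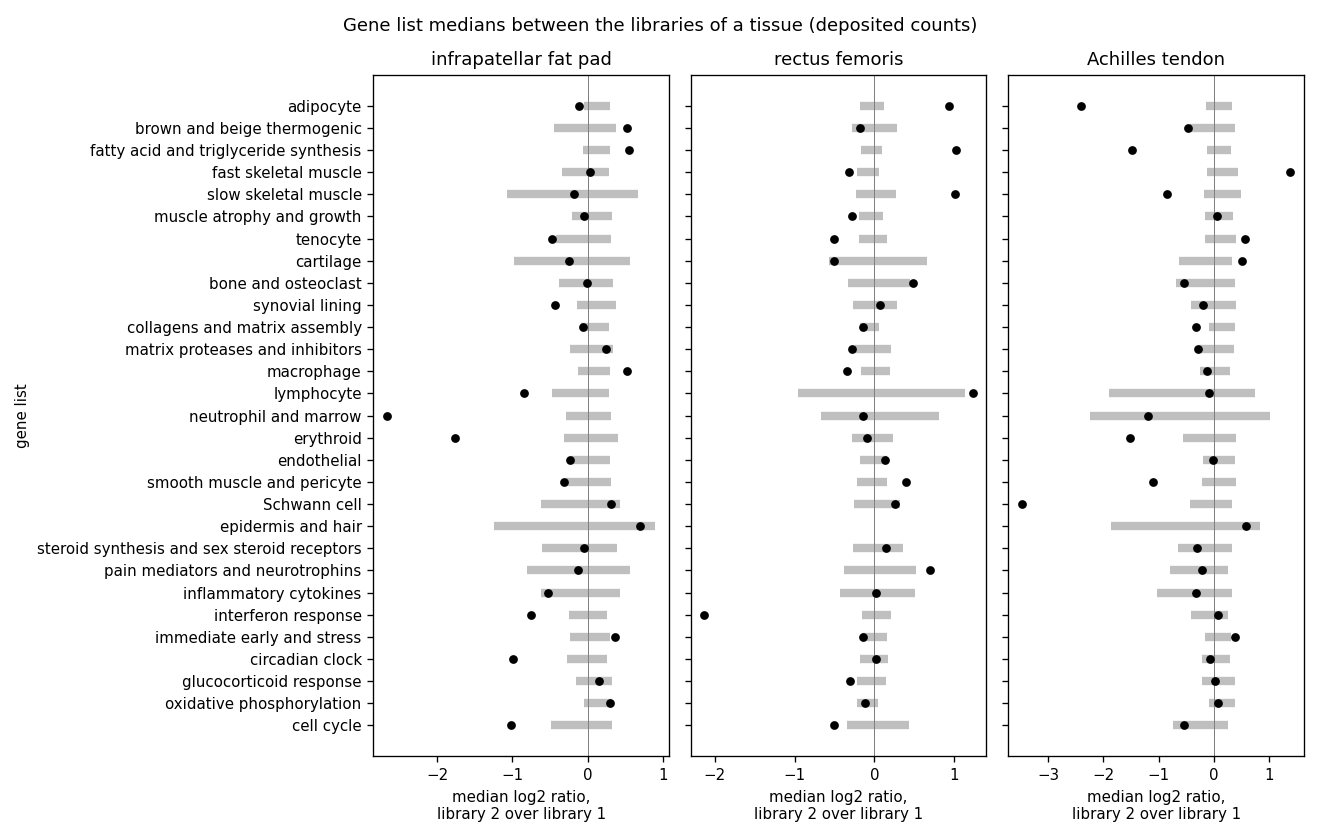
Median log2 ratio of counts, library 2 over library 1, for each gene list in each tissue (points), with grey bars for the central 95% of 10000 random lists matched on expression. In the fat pad 15 of 29 lists lay outside their bar, in muscle 15 of 28 and in tendon 13 of 29. Lists whose genes vary together leave the bar more easily than independently drawn genes.

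Each pair was also set against the spread between the libraries of the other 2 tissues, which compares the libraries and not conditions. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 31 of 16364 genes between the tendon libraries, 18 higher and 13 lower in library 2. Among them were Mbp with a log2 fold change of -3.97 ± 0.36 (adjusted p = 0.0272 by edgeR's test), Myh4 with 5.02 ± 0.55 (0.0296) and Actc1 with 4.01 ± 0.35 (0.0272). The same test called 0 genes between the fat pad libraries, with 1222 genes at an unadjusted p under 0.05 and 136 called by DESeq2, and 0 between the muscle libraries, with 291 and 22. Dbp in the fat pad had a log2 fold change of -3.90 ± 0.27 and an adjusted p of 0.0941 by edgeR's test. DESeq2 called 544 genes between the tendon libraries.

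A difference shared by the library numbers across the 3 tissues was tested with tissue in the model. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 15856 genes, with 272 at an unadjusted p under 0.05 and 9 called by DESeq2. Across genes, the log2 ratios of library 2 over library 1 correlated at r = -0.0516 between fat pad and muscle (rho -0.136), 0.0438 between fat pad and tendon (rho 0.103) and -0.332 between muscle and tendon (rho -0.365).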

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

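The tests on the mismatch between tables, on circulating blood, on bone and marrow and on the tendon libraries were chosen only after the results were seen. The values listed next come from the TPM columns of muscle and tendon, which served only as an alternative to the counts, and drew attention because list medians lay far from 0 there while the counts of the same library names had the other sign, except for the muscle tenocyte list, which was lower in library 2 in both units.

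In the tendon TPM columns the lymphocyte list had a median log2 ratio of library 2 over library 1 of 3.71, with 6 of 6 genes above 0, against -0.09 in counts. The bone and osteoclast list had 3.31 in TPM (8 of 8 genes above 0) and -0.55 in counts, with Bglap, the bone protein osteocalcin, at 0.633 and 1085 TPM and Ibsp, bone sialoprotein, at 81.0 and 954. The neutrophil and marrow list had 3.13 in TPM (4 of 4 genes above 0) and -1.19 in counts, with S100a8 at 3.25 and 133 TPM. The cell cycle list had 1.61 in TPM (12 of 12 genes above 0) and -0.53 in counts. In the muscle TPM columns the slow muscle list had -2.50 (0 of 10 genes above 0), against 1.01 in counts, with Myh7 at 8.35 and 0.368 TPM. The muscle tenocyte list had -1.60 in TPM (0 of 13 genes above 0), against -0.51 in counts, with Tnmd at 182 and 80.4 TPM.

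The first pattern weighed is this mismatch between the count and TPM columns of muscle and tendon. Names swapped within a tissue would put the correlation of the log2 ratios near -1, and the lower of the 2 correlations was -0.239 (rho -0.314). Gene lengths or the scaling to TPM would leave it near 1, as in the fat pad, and the higher was -0.231 (rho -0.388). Columns exchanged between the muscle and tendon tables would give a correlation near 1 or -1 across them, and the largest in size was 0.162 (rho 0.354). What stays open is that the columns may hold other libraries under the same names, for which no other table was at hand, and no biological explanation was tested, because a count and a TPM of 1 library cannot differ by biology.

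The second pattern is the lower level of neutrophil and erythroid genes in fat pad library 2. Circulating blood in library 1 lacks the granule precursors of the marrow, yet 6 such genes had a median of 709 counts in library 1 and 260 in library 2, with a median log2 ratio of -2.01 and a range of -3.29 to -1.57, which argues against blood alone. The most abundant, Mpo (4227 and 940 counts) and Elane (1470 and 608), are also in the neutrophil list, as is Prtn3, while the 3 outside it had log2 ratios of -1.78 (Ctsg, 543 and 194 counts), -2.25 (Fcnb, 476 and 122) and -3.29 (Ms4a3, 222 and 26). Bone and marrow carried along with library 1 would lower the bone list too, and its median of -0.0085 did not show such a fall. Its genes went both ways, with 3 at least 2-fold higher and 3 lower, among them Ibsp (-3.21) and Col10a1 (1.93). The list therefore cannot tell bone and marrow carried along apart from other causes. Whether the precursors in library 1 came with the dissection or from the animal stays open, and no biological explanation was tested, because the labels give no groups within a tissue.

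The third pattern is the higher level of fast muscle genes and the lower level of Schwann cell and adipocyte genes in tendon library 2, in the counts. The fast median lay 2.24 above the slow one, which more of a mixed muscle would not give. More of a fast muscle would raise the fast genes only. The rectus femoris was such a muscle, with 69991 and 74736 CPM of Myh4 and 1.30 and 4.75 of Myh7. More fast muscle in library 2 therefore stays open for the fast genes. It would not by itself lower the slow genes, whose median was -0.86 with 0 of 10 above 0, while the tenocyte median was 0.56. Dilution of all other cells by muscle RNA would lower the tendon genes as well, and the tenocyte median lay 4.03 above the Schwann cell median. A candidate explanation that remains is that the libraries took in different neighbouring tissue, with nerve, fat and slow fibres in library 1 and fast fibres in library 2, which was not tested further. No biological explanation was tested, because the labels give no groups within the tendon.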

How the results depend on the processing

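The TPM tests between tissues and the minimum of 10 counts in the lower library were chosen only after the data were seen, and the others before. Of 92 counts of genes or lists under an alternative, 70 lay within 1.5 times the reported count, 12 above and 10 below. Of 1245 values of named genes between tissues, 1156 kept direction and side of the threshold, 64 lost and 15 gained the call and 10 changed sign. Of 287 values of named genes between libraries, 189 moved by less than 1 on the log2 scale, 63 moved further and 35 changed sign. Depth limits genes near 3 counts per library. The cause of the changes listed next was not tested unless it is named.

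Leaving out each library in turn gave 6892 to 9671 genes for fat pad over muscle, 7825 to 8539 for fat pad over tendon and 19 to 4380 for tendon over muscle, where a library left alone is assumed to vary like the others. The lowest came without muscle library 2. Total counts gave 6367 genes for tendon over muscle. Camera with an estimated correlation called 0, 0 and 0 lists. TPM gave 8932, 9431 and 4526 genes for the 3 contrasts, and 7457, 6288 and 2089 genes were called in both units in the same direction.

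A replicate block gave 8649, 8650 and 2759 genes for fat pad over muscle, fat pad over tendon and tendon over muscle. The numbers were not taken to pair the libraries, since no label says that they do and the log2 ratios between tissues correlated across genes at -0.0516, 0.0438 and -0.332 in the counts.

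Between libraries, a minimum of 20 counts gave 3178 genes in the fat pad and 755 in muscle, and a minimum of 500 gave 549, 150 and 920 in fat pad, muscle and tendon, which tests more or fewer genes. TPM gave 559 genes in muscle and 827 in tendon. At least 10 counts in the lower library left 1416, 319 and 1456. Against the spread of the other pairs, DESeq2 called 136, 22 and 544 genes in fat pad, muscle and tendon. With a single other pair, the fat pad gave 100 against muscle, muscle gave 1 against the fat pad, and tendon gave 493 against muscle and 142 against the fat pad. DESeq2 called 9 genes by library number.

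For fat pad over muscle, Fasn turned from 0.75 to -0.013 without muscle library 1 and -0.25 in TPM. For fat pad over tendon, Esr1 turned from -0.30 to 0.31 and Lep from -1.19 to 1.39 without tendon library 1, and Plin1 from 1.26 to -0.082 in TPM. For tendon over muscle, Fasn turned from -0.37 to 0.39 with total counts, 1.32 without muscle library 2 and 0.46 without tendon library 2. Without tendon library 1, Adipoq turned from 1.70 to -0.88 and Plin1 from 2.41 to -0.54. None of these values of changed sign passed the threshold. For fat pad over tendon, Plin1 (4.24) and Fasn (3.24) gained the call without tendon library 1, and Lep (-2.07) without tendon library 2, as did Plin1 (3.31) for tendon over muscle. Over all left-out libraries, Fasn ran from -0.013 to 2.43 for fat pad over muscle, Esr1 from -0.71 to 0.31, Lep from -2.07 to 1.39 and Plin1 from 0.35 to 4.24 for fat pad over tendon, and for tendon over muscle Fasn from -2.46 to 1.32, Adipoq from -0.88 to 2.65 and Plin1 from -0.54 to 3.56.

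In TPM the following log2 ratios between muscle libraries had the other sign: H2ac18 -10.41, Oxtr -0.47, Fxyd3 -0.052, Zfp961 -0.36, Ngfr -0.51, Cd3e -0.076, Rsl1 0.12, Apol9b 0.96, Ifit3 0.47, Apol9a 0.33, Ifi44 0.062, Ifit3b 0.26, Irf7 0.35, Isg15 0.40 and Slfn1 0.40. Between tendon libraries they were Igfn1 -0.77, Zfp708 -0.11, Pcdhga10 -0.31, Mss51 -2.38, Myh4 -2.31, Mybph -1.74, Pvalb -1.57, Odf3l2 -4.55, Fgfbp1 -0.26, Nol4 -0.052, Tspan8 -1.10, Col6a5 1.96, Mrgprg 1.33, Pipox 0.34, Cldn19 0.018, Ocln 0.51, Tmem229a 0.64, Lctl 0.020, Ugt8a 0.18 and Mal 0.16. The TPM columns there did not follow the counts for the same names.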

Other observations

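The test on library numbers was chosen only after the result was seen, while the test on clock-driven genes was set before those genes were looked at.

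Some genes of pain signalling and thermogenesis stood apart between the fat pad libraries in either direction, with no replicate check. Ptges, which makes prostaglandin E, had 3496 and 13220 counts, a log2 ratio of library 2 over library 1 of 1.61 (95% interval 1.56 to 1.67). Artn, a neurotrophic factor, had 0 and 84 counts, at least 22.7-fold higher, while Tac1, the precursor of substance P, had 38 and 0, at least 15.6-fold lower. The pain mediator list had 4 of 13 genes at least 2-fold higher and 4 lower, with a median of -0.13 at percentile 40.6 of the random lists, whose central 95% ran from -0.81 to 0.57. The inflammatory cytokine list had -0.52, with Il1b at 98 and 3 counts. The thermogenic list had a median of 0.52, with 1 of 10 genes at least 2-fold higher, Ucp1, the uncoupling protein of brown fat (8 and 164 counts, 3.78), and 1 lower, Dio2, which activates thyroid hormone (264 and 147 counts, -1.14). Hsd17b7, which takes part in oestradiol and cholesterol synthesis, had 201 and 1013 counts (2.02, 95% interval 1.81 to 2.26), and the sex steroid list a median of -0.04. The oestrogen receptor Esr1 had -0.53 (95% interval -0.62 to -0.45).

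In the tendon counts the smooth muscle and pericyte list had a median of -1.09, with 6 of 10 genes at least 2-fold lower and Myh11, the smooth muscle myosin, at -2.87. The endothelial list did not follow it, at -0.0085 with 0 of 10 genes at least 2-fold higher or lower, and had 0.13 in muscle and -0.23 in the fat pad. The tendon erythroid list had -1.51, with 5 of 6 genes at least 2-fold lower, and the cartilage list 0.50. In the muscle counts the smooth muscle and pericyte list had 0.39 and the pain mediator list 0.70, and both turned in the TPM columns, to -0.70 and -0.38. The endothelial medians turned there as well, to 0.26 in tendon and -0.39 in muscle. Immediate early genes had medians of 0.36 in the fat pad, -0.15 in muscle and 0.38 in tendon, and glucocorticoid response genes 0.15, -0.31 and 0.01. The muscle atrophy list had -0.04, -0.28 and 0.05. When scaled by total counts, the tendon values of the glucocorticoid and atrophy lists turned to -0.15 and -0.11, and in the TPM columns to -0.20 and -0.039.

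The clock genes of the fat pad split as they do between opposite hours of the day, so a hypothesis is that its libraries were taken at different phases of the circadian clock. Clock-driven genes outside the list were set to move apart by at least 1, and the log2 ratio of Nfil3 lay 1.99 above the median of Usp2, Wee1 and Lonrf3. Usp2 (4819 and 2522 counts, -1.24), Wee1 (2479 and 1797, -0.77) and Nfil3 (707 and 2043, 1.23) moved as this phase difference predicts, while Lonrf3, 1 of the 3 genes named beforehand with Dbp's phase, went the other way (36 and 158 counts, 1.78). The result is consistent with a phase difference with that exception, whose phase was assigned from general knowledge and not checked in adipose tissue, so that it may be misplaced. The labels used here give no hour of collection, and an effect on the clock itself stays open.

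A second hypothesis was that the library number marks a condition or an animal shared by the 3 tissues. The log2 ratios of library 2 over library 1 would then correlate above 0.1 between every pair of tissues, and the lowest correlation was -0.332, between muscle and tendon. If the count columns hold the libraries they name, the ratios did not move together across all genes in the 3 tissues. The correlation cannot decide on a shared condition that moves fewer genes, because cell type lists moved apart between the pairs. The adipocyte list, for example, had medians of 0.93 in muscle and -2.41 in tendon. A condition that moves different genes in each tissue stays open as well.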
